A study of Homo sapiens with 4 samples.

How the data were processed

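The series used methylated RNA immunoprecipitation sequencing (MeRIP-seq), in which fragmented RNA is pulled down with an antibody against N6-methyladenosine (m6A) and sequenced beside the unselected RNA, called the input. The cells were PEO1, an established ovarian cancer line with a BRCA2 mutation, and a derivative made resistant to PARP inhibition by stepwise exposure to olaparib. Each of the 2 cell lines gave 1 pulldown and 1 input library, so there were 4 libraries and 1 library per group. Per the labels' protocols, total RNA was fragmented with zinc ions and libraries were made with the ScriptSeq Complete Gold kit.

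The deposited table holds 1 value per gene and library for 57736 Ensembl gene IDs. The values are whole numbers that sum to a different total in each library, and they were taken as estimated counts that the authors had rounded. RSEM 1.2.3, HOMER and the hg19 genome build are named in the submitters' processing notes, which give neither their role nor their order. RSEM divides a read that fits several genes between them by estimation, and 110 of the 14646 gene IDs with at least 20 reads in a library carried counts equal to another ID's in all 4 libraries. The aligner, the gene annotation release and any filter on reads are not given in the sources used here. Every row carried an Ensembl gene ID, so no count was set aside as unassigned.

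The deposited table does not pair its IDs with gene names, and 0 of its IDs matched the reference gene table at hand, whose Ensembl field is empty for all 59792 genes. FZD10, the gene in the series title, and the 20 gene lists fixed before the data were examined could therefore not be located, and they are not analysed here. The table holds no regions or coordinates, so regions gained or lost and the m6A sequence motif are not analysed here either. A count over a whole gene also averages a methylated site with the unmethylated rest of the transcript.

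From the counts, log2 CPM values were computed with the sum over all gene IDs as the library size. A pseudocount of 1 read per library on average, scaled to library size, was added first. Enrichment was the log2 ratio of pulldown to input within a cell line. The change in m6A enrichment was the difference of the 2 log2 enrichments, resistant minus parental, and is a ratio of ratios. Pulldown and input were also each compared between the lines. A gene entered a comparison with at least 20 reads summed over the 2 libraries compared. For the ratio of ratios, it needed 20 reads over the inputs and 20 over the pulldowns.

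With 1 library per group there is no replicate error and no p-value is given. A gene was counted as different by size alone, at 2-fold or more (1 on the log2 scale). Beside this, 95% counting intervals were computed, as exact conditional binomial (Clopper-Pearson) intervals for 2 libraries and as log-normal intervals with 0.5 reads added to each count for the ratio of ratios. They cover counting error only, compare these libraries and not the conditions, and leave out amplification duplicates and the uncertainty of the read assignment. A fold against 0 reads was bounded with 3 reads in that library, which is 0.377 CPM in the parental pulldown, 0.323 CPM in the resistant pulldown, 1.48 CPM in the parental input and 1.09 CPM in the resistant input.

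The intervals were tested on simulated counts for the real genes and library sizes with 200 changed genes. The counts were drawn with counting error only, which the intervals assume. The test therefore checks the computation and not how the intervals cover other variation between libraries. For the ratio of ratios over 12000 genes, the interval lay above 1 in 79.0% of genes simulated with a 2-fold change and in 97.0% of those with a 4-fold change. In that comparison, 94.9% and 95.1% of the intervals held the true value. For the input comparison over 12971 genes, the interval lay above 1 in 88.5% of 2-fold changes and in 100% of 4-fold changes. An interval above 1 is a weaker demand than a size of 2-fold or an interval wholly past 2-fold. These shares are therefore not the rates at which the counts given below find changed genes. The numbers of genes that counting error alone puts past 2-fold were estimated from 20 simulated data sets without a difference between the lines.

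The rule for named genes had asked for the 12 largest changes each way among genes with a symbol. It left out clone-type symbols and those starting with LOC, LINC, MIR, SNOR or RNU, among others. IDs alone do not allow that screen, so the IDs named here may include such genes. Without symbols, only the 2 largest changes each way past the read minimum are given per comparison, by ID. They were ranked by the log2 change with the pseudocount. In a tie, the later row was taken for rises and the earlier row for falls. The folds printed for genes with 0 reads replace only the 0, would rank the genes differently, and can exceed the lower end of the 95% counting interval, which also covers the other counts. IDs chosen after their values were seen are marked as such. Alternatives were pseudocounts 0.1 and 5 times the main one, centring of each comparison on its median, TMM factors from edgeR 4.0.16 (R 4.3.3), no read minimum, a read minimum 5 times stricter, and folds of 1.5 and 4. These were fixed before the data were examined. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.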

Results

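m6A pulldown and input RNA were sequenced from parental and PARP inhibitor-resistant PEO1 cells. The parental pulldown held 7967983 counts and the resistant pulldown 9280079. The inputs were shallower, with 2029349 counts in the parental and 2753980 in the resistant cells. Of 57736 gene IDs, 30065 had 0 reads in all 4 libraries. At least 10 reads were counted for 14621 genes in the parental pulldown, 14989 in the resistant pulldown, 12629 in the parental input and 13215 in the resistant input. The same gene ID was the most abundant in both pulldowns and took 8.41% of the parental pulldown (exact 95% interval 8.39 to 8.43) and 7.12% of the resistant pulldown (7.10 to 7.13). Genes are given by Ensembl ID because the deposited table does not pair IDs with names.

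The first question was which genes the m6A antibody enriched in each line. In parental cells, 4091 of 14287 genes (28.6%) were at least 2-fold higher in the pulldown than in the input, and 5914 (41.4%) were at least 2-fold lower. In resistant cells, 4486 of 14798 genes (30.3%) were at least 2-fold higher and 6311 (42.6%) at least 2-fold lower. The median log2 enrichment was -0.43 in parental and -0.47 in resistant cells, and the 5th to 95th percentiles ran from -3.36 to 3.62 and from -3.43 to 4.19. The 95% counting interval lay wholly past 2-fold enrichment for 2623 genes in parental and 3219 in resistant cells. It lay wholly past 2-fold depletion for 4598 and 5104 genes. These numbers are relative to the library total. Genes higher in the pulldown made up 40.9% of the genes past 2-fold in parental cells, 50.1% after centring on the median gene and 59.2% with TMM factors. The corresponding shares in resistant cells were 41.5%, 50.8% and 57.4%. TMM factors raised the median log2 enrichment by 0.82 in parental and by 0.78 in resistant cells.

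The enriched genes were largely shared between the lines. The overlap was taken over the 11805 genes past the read minimum in both lines and for the ratio of ratios. The latter leaves out genes with under 20 reads over the inputs, also where their pulldown is high. Of the 11805 genes, 2757 were at least 2-fold enriched in parental cells, and 2299 of these (83.4%) were also at least 2-fold enriched in resistant cells. Independent lists of these sizes would share 675. Of 5293 genes at least 2-fold depleted in parental cells, 4737 (89.5%) were depleted in resistant cells, against 2418 for independent lists. Across these genes, which are not independent replicates, log2 enrichment in the 2 lines correlated with a Pearson r of 0.88 and a Spearman rho of 0.90. The lines share no library in this comparison. Levels in the 2 pulldowns correlated across 12000 genes with a Spearman rho of 0.96 and levels in the 2 inputs with 0.89. Pulldown and input of the same line correlated with 0.53 in parental and 0.52 in resistant cells.

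**Figure D1:**
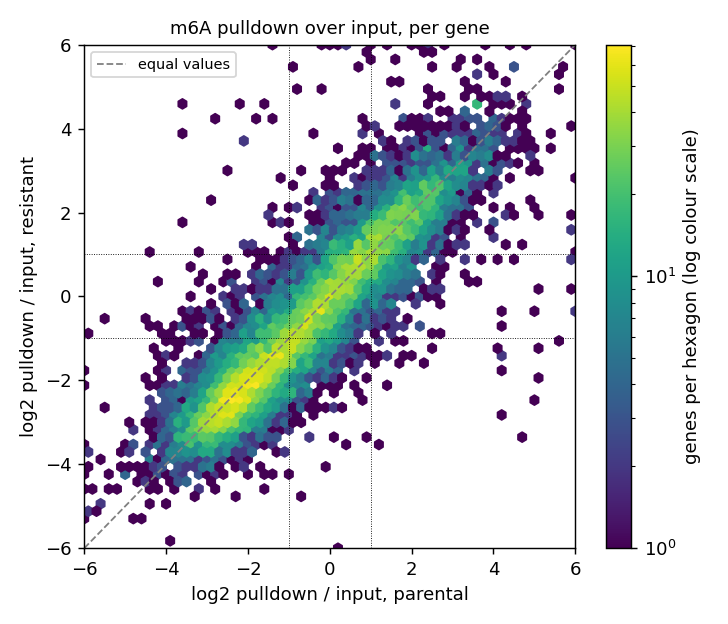
Log2 ratio of m6A pulldown to input per gene in parental (horizontal axis) and resistant cells (vertical axis), for 11805 genes with 1 library per group; colour gives the number of genes per hexagon on a log scale, dotted lines mark 2-fold, and values beyond the axes are drawn at the edge. Genes lie along the dashed line of equal values (Spearman rho 0.90), with 2299 genes in the upper right corner and 4737 in the lower left corner past the 2-fold lines.

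The main comparison asked how m6A enrichment differed between resistant and parental cells once the input was taken into account. Of 12000 genes, 1178 (9.82%) had at least 2-fold higher enrichment in resistant cells and 1015 (8.46%) at least 2-fold lower enrichment. The median log2 change was -0.03, with quartiles at -0.45 and 0.42. The counting interval lay wholly past 2-fold for 256 genes with higher and 110 genes with lower enrichment. Between the pulldowns alone it did so for 302 higher and 301 lower genes, and between the inputs for 339 higher and 470 lower genes. A lower resistant input raises the change in enrichment, so the difference between 256 and 110 does not by itself show a gain of m6A. Counting error alone put on average 154 genes past 2-fold higher and 182 past 2-fold lower in data simulated without a difference. At a read minimum 5 times stricter, 206 genes were higher and 200 lower. The simulated numbers of genes past 2-fold were taken at the main read minimum only. They are therefore no reference for the 206 and 200 genes.

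The input passed 2-fold while the pulldown did not in 672 of the 1178 genes with higher and 515 of the 1015 genes with lower enrichment. Over all 12000 genes tested, the pulldown was within 2-fold in 91.6% and the input in 80.8%. Among the 1178 genes with higher enrichment in resistant cells, the pulldown was within 2-fold of parental cells in 989 (84.0%) and at least 2-fold higher in 144. The input was at least 2-fold lower in 764 of them. Among the 1015 genes with lower enrichment, the pulldown was within 2-fold in 816 (80.4%) and at least 2-fold lower in 152, and the input was at least 2-fold higher in 586. Genes whose pulldown alone passed 2-fold, with the input within 2-fold, numbered 91 and 120 in the 2 directions. The median log2 change of the genes with higher enrichment was 0.28 in the pulldown and -1.30 in the input. For the genes with lower enrichment the medians were -0.31 and 1.16. These genes were chosen by a ratio that holds the inputs. The shallower inputs carry more counting error (median half-width of the counting interval 0.56 on the log2 scale, against 0.39 for the pulldown). That alone favours genes whose input moved. How counting error would split these genes was not simulated, so the split does not show what drove the changes.

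Ranked by log2 change with the pseudocount, the 2 largest changes in enrichment each way were in genes with 0 reads in an input. The folds given are bounds with 3 reads in place of 0, which order genes differently. ENSG00000236552 had 2716 pulldown and 716 input reads in parental cells and 1303 pulldown and 0 input reads in resistant cells. Its enrichment was at least 133-fold higher in resistant cells with 3 reads in place of 0, and the 95% counting interval began at 50.0-fold, although its pulldown level was 2.43-fold lower (95% counting interval 2.27 to 2.60). ENSG00000264322 had 363 pulldown and 230 input reads in parental cells and 248 pulldown and 0 input reads in resistant cells, at least 61.0-fold higher enrichment (interval from 22.8-fold). Its pulldown level was 1.70-fold lower (1.45 to 2.01). Both rises thus come from the 0 resistant input reads and not from a higher pulldown. The counting intervals do not cover reads missed in that input or assigned to other genes, so neither rise shows a gain of m6A. In the other direction, ENSG00000243960 had 34 pulldown and 0 input reads in parental cells and 6 pulldown and 22 input reads in resistant cells. Its enrichment was at least 35.7-fold lower in resistant cells (interval from 11-fold). ENSG00000232472 had 42 pulldown and 0 input reads in parental cells and 19 pulldown and 35 input reads in resistant cells, at least 22.1-fold lower enrichment (interval from 7.74-fold).

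Pulldown signal was also compared between the lines without the input. Of 14810 genes, 895 (6.04%) were at least 2-fold higher in the resistant pulldown and 858 (5.79%) at least 2-fold lower. The counting interval lay wholly past 2-fold for 302 and 301 genes, and simulations with counting error alone gave 66.7 and 52.4 genes past 2-fold on average. The largest higher values were ENSG00000215020, with 0 parental and 108 resistant pulldown reads (at least 30.9-fold), and ENSG00000200347, with 0 and 96 reads (at least 27.5-fold). The input of ENSG00000200347 differed the other way, from 218 parental to 53 resistant reads (5.58-fold lower, 4.12 to 7.69). Its m6A enrichment was thus at least 153-fold higher in resistant cells (interval from 56.1-fold). The input of ENSG00000215020 held 3 parental and 15 resistant reads, a ratio of 3.68 with a counting interval of 1.04 to 19.9. The largest lower values were ENSG00000136542, with 165 parental and 0 resistant pulldown reads (at least 64.1-fold), and ENSG00000176046, with 116 and 0 reads (at least 45.0-fold). Both also had 0 reads in the resistant input, against 9 and 44 reads in the parental input.

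Input libraries measured RNA abundance. Of 12971 genes, 1328 (10.2%) were at least 2-fold higher in resistant cells and 1420 (10.9%) at least 2-fold lower. The counting interval lay wholly past 2-fold for 339 and 470 genes, and counting error alone gave 132 and 81.9 genes past 2-fold on average. The largest higher values were ENSG00000229212, with 0 parental and 100 resistant input reads (at least 24.6-fold), and ENSG00000267261, with 0 and 89 reads (at least 21.9-fold). The pulldown of ENSG00000229212 held 1563 parental and 2275 resistant reads, a 1.25-fold difference (1.17 to 1.33), and that of ENSG00000267261 held 0 reads in both lines. The largest lower values were ENSG00000236552, given above, at least 324-fold, and ENSG00000227063, at least 104-fold. ENSG00000227063 had 231 parental and 0 resistant input reads and no pulldown read in either line. The resistant pulldown of ENSG00000236552 held 1303 reads, 2.43-fold below the parental level, so its 0 input reads do not show that the RNA was absent.

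Genes that passed 2-fold in the same direction in pulldown and input were more frequent than independent lists would give. Among 12000 genes, 502 were higher in the pulldown, 1080 in the input and 252 in both, against 45.2 for independent lists. Lower values were found for 512 genes in the pulldown, 1230 in the input and 216 in both, against 52.5. Enrichment changed by under 2-fold in 199 of the 252 genes higher in both assays and in 163 of the 216 genes lower in both. Opposite directions were found for 24 genes with a higher and 47 with a lower input.

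The 4 genes with the most reads among those 2-fold apart in both assays, 2 in each direction, were chosen after their values were seen. ENSG00000115414 was 8.12-fold higher in the resistant input (2163 against 17565 CPM, counting interval of the ratio 7.87 to 8.38) and 6.68-fold higher in the pulldown (6.42 to 6.95). It was depleted by the antibody in both lines, with a log2 enrichment of -2.62 in parental and -2.90 in resistant cells. ENSG00000182197 was 2.35-fold higher in the input (2.07 to 2.67) and 2.49-fold higher in the pulldown (2.40 to 2.58). ENSG00000115461 was 9.17-fold lower in the resistant input (1599 against 174 CPM, 8.33 to 10.1) and 12.8-fold lower in the pulldown (12.4 to 13.3). ENSG00000184208 was 2.57-fold lower in the input (2.04 to 3.25) and 2.03-fold lower in the pulldown (1.96 to 2.10). The fold of enrichment, resistant over parental, was 0.823 for ENSG00000115414, 1.06 for ENSG00000182197, 0.715 for ENSG00000115461 and 1.27 for ENSG00000184208.

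Across 12000 genes, the change in m6A enrichment and the change in input RNA ran in opposite directions, with a Pearson r of -0.79 and a Spearman rho of -0.71. The inputs enter both quantities with opposite signs, and data simulated with counting error alone gave a mean r of -0.80. The covariance was -0.775, against a mean of -0.101 in the simulations. The change in pulldown, which shares no library with the change in input, correlated positively with it (r = 0.40, rho = 0.36), against a simulated mean r of -0.002. Over 2241 genes with at least 400 input reads, the r of pulldown and input changes was 0.54, the slope was 0.48, and the r of enrichment and input changes was -0.57, against a mean of -0.72 in the simulations. Genes are not independent replicates in these correlations.

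**Figure D2:**
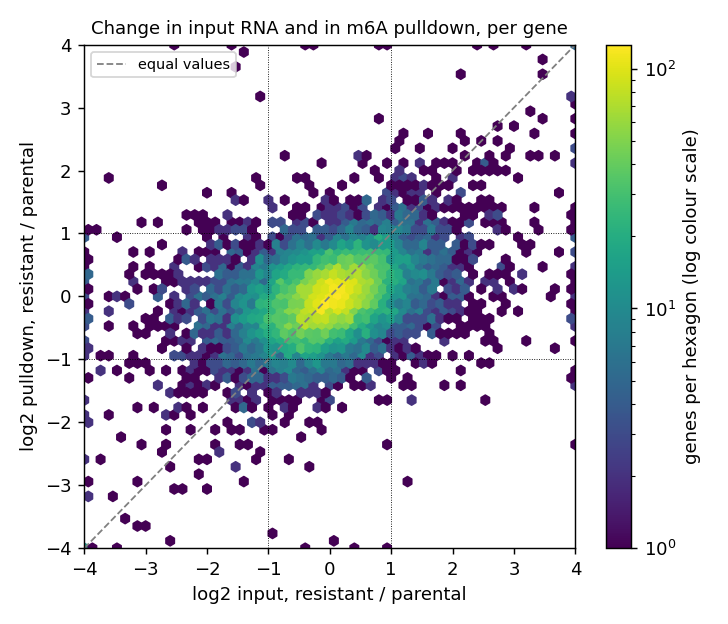
Log2 ratio of resistant to parental cells per gene in the input (horizontal axis) and in the m6A pulldown (vertical axis), for 12000 genes with 1 library per group; colour gives the number of genes per hexagon on a log scale, dotted lines mark 2-fold, and values beyond the axes are drawn at the edge. The input values spread more widely (SD across genes 1.02) than the pulldown values (SD 0.65), and the cloud is flatter than the dashed line of equal values. The inputs were shallower. Over the 2241 genes with at least 400 input reads the SDs were closer, at 0.57 for the input and 0.51 for the pulldown.

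The inputs differed in how many genes they reached. The parental input listed 20080 genes with at least 1 read and the resistant input 18128, although the resistant total was higher. The 1-read genes numbered 1994 in the parental and 905 in the resistant input, against 2707 and 2782 in the pulldowns. In 7 bins of genes set by pulldown level alone, the share of genes with 0 input reads was higher in the resistant input in 7 of 7 bins, and the Wilson 95% intervals were apart in 5. For genes at 0.5 to 1 CPM in the pulldowns, 45.4% had 0 reads in the resistant input (43.1 to 47.7) and 35.7% in the parental input (33.5 to 37.9). For genes at 8 to 16 CPM the shares were 5.59% (4.74 to 6.59) and 2.63% (2.05 to 3.35).

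**Figure D3:**
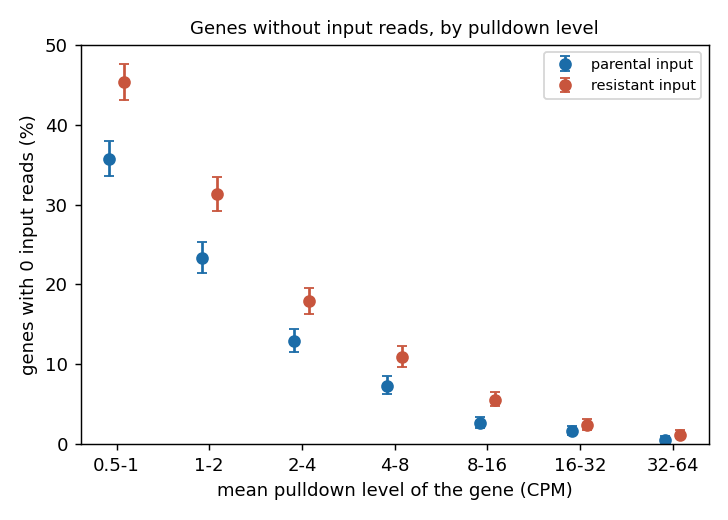
Share of genes with 0 input reads (vertical axis, percent) by mean pulldown level of the gene in CPM (horizontal axis, 7 bins), for the parental and the resistant input, 1 library each; bars are Wilson 95% intervals over genes. The resistant input lies above the parental input in all 7 bins, from 45.4% against 35.7% in the lowest bin to 1.15% against 0.57% in the highest.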

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

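Some genes were enriched by the antibody in 1 line and depleted in the other, with 1 library each, and the difference was not tested. There were 24 genes at least 2-fold enriched in parental and at least 2-fold depleted in resistant cells, and 33 genes with the opposite order, among 11805 genes. These calls depend on the scaling, as a check chosen after seeing the data showed. Centring on the median gene gave 20 and 34 genes, of which 10 and 23 were among those above, and TMM factors gave 18 and 32, of which 7 and 18 were. Of the genes named in the text, ENSG00000264322 was 2.49-fold depleted in parental cells and at least 24.5-fold enriched in resistant cells, at least a 61.0-fold difference (95% counting interval from 22.8-fold). Its parental log2 enrichment was -1.31 as reported, -0.88 after centring and -0.48 with TMM factors, so that it was not 2-fold depleted under either. The next 2 genes stayed past 2-fold in both lines under both scalings. ENSG00000243960 was at least 2.89-fold enriched in parental and 12.4-fold depleted in resistant cells, at least a 35.7-fold difference (from 11-fold). ENSG00000232472 was at least 3.57-fold enriched in parental and 6.21-fold depleted in resistant cells, at least a 22.1-fold difference (from 7.74-fold). Each of these 3 genes had 0 reads in an input.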

How the results depend on the processing

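Of 100 counts recomputed under 10 alternatives, 59 stayed within 1.5 times the reported count and 41 moved further. The alternatives that leave out genes with 0 reads or use the counting interval were chosen after seeing the data. Centring on the median, TMM factors and both pseudocounts moved no count past 1.5 times. Counts are given as higher and lower. Without a read minimum they were 6734 and 10968 for parental enrichment, 8000 and 9477 for resistant enrichment, 7145 and 4638 for the change in enrichment, 2728 and 2411 for the pulldown and 3956 and 6274 for the input. With the read minimum 5 times stricter, depleted genes fell to 3298 in parental and 3803 in resistant cells, and the counts were 206 and 200 for the change in enrichment, 415 and 376 for the pulldown and 364 and 337 for the input. At a fold of 1.5 they were 2313 and 2272 for the change in enrichment, 2208 and 2167 for the pulldown and 2723 and 2763 for the input. At a fold of 4 they were 2223 and 3538 for parental enrichment, 2661 and 3930 for resistant enrichment, 293 and 187 for the change in enrichment, 161 and 179 for the pulldown and 345 and 384 for the input. With the counting interval wholly past 2-fold, 2623 genes were enriched in parental cells, and the counts were 256 and 110, 302 and 301, and 339 and 470 for the change in enrichment, the pulldown and the input. Fewer genes qualify by construction under the stricter settings and more under the looser ones. The correlation of the changes in enrichment and input, -0.79, was -0.82 and -0.78 with the smaller and larger pseudocount and -0.77 with TMM factors. Without a read minimum it was -0.88, and without genes at 0 reads -0.75. It was -0.65 where only the minimum over the inputs was raised, to 100 reads, with 20 over the pulldowns. The cause was not tested. The correlation turned to 0.40 when the pulldown ratio, which shares no library with the input, replaced the ratio of ratios. The 12 log2 changes by which IDs were ranked kept their direction under each pseudocount and scaling but depend on the pseudocount, because each has a library at 0 reads. They moved towards 0 by 2.23 to 2.89 with the larger pseudocount and away from 0 by 3.30 to 3.56 with the smaller one. The larger one took the 4 pulldown values out of their counting intervals and none of the other 8. Summing the rows of a gene was not run because each ID has 1 row, and results for FZD10, gene lists, regions and motifs were not run for want of names and coordinates. The median half-width of the counting interval, which depth sets, was 0.65 on the log2 scale for the change in enrichment, 0.56 for the input and 0.39 for the pulldown.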

Other observations

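Of the tests below, the pulldown test of absent RNA and the share of genes with 0 reads by pulldown level were set down before their result was seen, and the others were chosen afterwards.

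Changes in m6A enrichment ran against changes in input RNA across genes. Over 2241 genes with at least 400 input reads the covariance was -0.171, against a lowest value of -0.013 simulated with counting error of the shared inputs alone. These values argue against counting error alone as the whole cause in those genes. Variation between single libraries beyond counting would also give that gap and stays open. Another candidate explanation is that pulldown follows RNA level less than proportionally, with a slope of pulldown change on input change of 0.479 in those genes, but error in the inputs flattens the slope too, and without repeat inputs these cannot be told apart. Whether resistance itself altered m6A in these genes stays untested, as each line gave 1 library of each kind.

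The resistant input reached fewer genes than the parental input. Sequencing depth argues the other way, since the resistant input listed 18128 genes from 2753980 counts and the parental input 20080 from 2029349. RNA absent from resistant cells was not the whole cause in the genes tested, which had 1 to 9 parental input reads and at least 20 pulldown reads. The 569 with 0 resistant input reads and the 1697 with reads differed by -0.27 in median log2 pulldown change. The bootstrap 95% interval was -0.36 to -0.18, where absence predicted -1 or less. That interval lies below 0, and a median does not show a subset, so lower or absent RNA in some of these genes stays open. Genes with fewer pulldown reads were not tested. Fewer distinct RNA fragments sampled in the resistant input and a wider scatter of single reads in the parental input both stay open. The larger share of genes with 0 reads in the resistant input in 7 of 7 bins of pulldown level restates the pattern and does not decide between them.

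In the inputs, 153 genes had 0 reads where the other input predicted at least 20, of which 116 were in the resistant and 37 in the parental input. The prediction scales by library total, so a resistant 0 qualifies from fewer reads in the other input than a parental 0. The genes able to qualify were not counted, so 116 and 37 do not compare rates. In 65 of the 153 genes the pulldown of the same line was also predicted to hold at least 20 reads. It held over 0.5 times the predicted count in 38 and under 0.1 times in 10.

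Among gene IDs with at least 20 reads in a library, 110 IDs in 41 sets had equal counts in all 4 libraries. The largest set held 16 IDs, each with 1088 parental pulldown, 1536 resistant pulldown, 24 parental input and 19 resistant input reads. None of the IDs named in the text was in such a set. Equal counts do not reveal reads divided unevenly between IDs, so the named IDs may still share reads with others.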
